A study of Mus musculus with 8 samples.

How the data were processed

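RNA was measured in whole mouse lung by bulk RNA sequencing. The labels give 8 libraries from C57BL/6 mice aged 3 to 5 months, 4 from mice with the Alb-Cre driver alone (Alb-Cre) and 4 from mice with the same driver and floxed Hif1a and Bmal1 alleles (BHLKO). Bmal1 is listed under its gene symbol Arntl. Alb-Cre is active in hepatocytes, so the targeted organ is the liver and the lung is an organ outside it. All mice had spent 2 weeks in 12 h light and 12 h dark before the lights were left off on the day of collection, and all samples carry circadian time 16. Per the labels' protocols, the tissue was snap-frozen, ground in a bead beater and extracted with a phenol-based reagent, and libraries followed standard Illumina protocols. Whether the kit kept strand, and which gene annotation was counted, are not given in the sources used here.

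Per the submitters' processing notes, the tools were cutadapt, STAR 2.5.2b, HTSeq and DESeq2 and the genome build was mm10, with no role or order stated for any of them. The table deposited by the authors lists 15960 gene symbols. It holds whole-number read counts for each library, per the file headers, and beside them a normalized signal that the authors made by dividing each library's counts by 1 constant. Recomputed DESeq2 size factors equalled those constants. Each listed gene had at least 6 counts in at least 1 library, so genes below that level are not analysed here. The normalized columns served only to identify that scaling, and all tests started from the counts. All 16 columns of per-sample values were matched to a sample by the name in its description, and replicates carry the numbers of the descriptions (1, 2, 4 and 5 for Alb-Cre, 2, 3, 4 and 5 for BHLKO).

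Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter by group, and a robust quasi-likelihood F test of BHLKO against Alb-Cre with no further covariate. The filter kept 13517 genes, which hold 99.899% of all counts. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Levels are CPM, counts divided by the TMM-scaled library size and multiplied by 1e6, as mean ± SD over 4 libraries, and log2 fold changes are given ± SE, with the SE taken from the fold change and the F statistic. Total counts ran from 6838427 to 15430372 per library. A gene with 0 counts in a group was set against a floor of 3 counts over that group. Counting intervals and floors rest on counts summed over the libraries of a group, so they cover counting error only and leave out the spread between libraries. Reads carry no molecular identifiers, so copies of a fragment count separately and counting error may be larger. On simulated counts with 200 changed genes among the 13517, edgeR recovered 26.9% of genes changed 1.5-fold, 65.7% changed 2-fold and 92.4% changed 4-fold, and 6.8% of its calls were false. DESeq2 1.42.0 made 15.5% false calls on the same simulation and limma-voom (limma 3.58.1) 4.1%. The simulation was a single draw of independent genes with dispersions estimated by edgeR, so it does not rank the tools on the real counts.

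Before the data were examined, 43 gene lists were fixed for lung cell types, neighbouring tissues, blood, vascular signalling, hypoxia, the clock and stress responses, and the genes to be named were fixed by a rule. The rule takes Arntl, Hif1a and the sex-linked genes; the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM and group values that do not overlap, passing over unnamed gene models; and up to 4 members with the smallest p of each list that changed or had at least 2 called members. Other genes in the text are single called members of a list or were singled out after their values were seen, as stated there. The list of mitochondrially encoded genes had no listed member. The 39 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. In the simulation camera called the 1 list that had been lowered 2-fold and 1 other list. Simulated genes were drawn independently, whereas the estimated correlation in the real lists reached 0.85 (B cells and plasma cells). The simulation therefore does not measure the false calls of camera in these lists. Arntl and Hif1a were also compared by an exact two-sided permutation test over the 70 orderings of 4 against 4, whose smallest possible p is 0.0286.

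Gene positions are from GENCODE release M21, which uses the mm10 assembly, and 15642 of the 15960 symbols (98.01%) received one. The alternatives tried were other scalings, filters, tests and thresholds, replicate numbers as a block, 1 surrogate variable (sva 3.50.0), and leaving out each library in turn. Leaving out genes by position and testing list scores per library were added after the data were seen.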

Results

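The data are gene counts from the lungs of 4 Alb-Cre and 4 BHLKO mice at circadian time 16. The series asks how the lung is affected when BMAL1, the core clock activator, and HIF1A, the oxygen-regulated transcription factor, are both missing from hepatocytes, in a model its title links to hepatopulmonary syndrome. The single comparison is BHLKO against Alb-Cre lung. Total counts per library were between 6838427 (Alb-Cre replicate 2) and 15430372 (Alb-Cre replicate 5). The labels number the libraries without saying that each came from a separate animal, and p-values measure the spread between these libraries. The first principal component held 28% of the variance and separated the genotypes, with Alb-Cre replicate 5 (−6.46) between the other Alb-Cre libraries (−32.34 to −26.25) and the BHLKO libraries (14.64 to 29.98).

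Neither targeted gene differed detectably in the lung. Arntl (chromosome 7, 113207465 to 113314126) was at 6.54 ± 1.37 CPM in Alb-Cre and 7.6 ± 2.5 CPM in BHLKO (SD, n = 4 each; exact two-sided permutation p = 0.571; log2 fold change 0.22 ± 0.26). Hif1a (chromosome 12, 73901375 to 73947530) was at 12.8 ± 1.95 and 13.5 ± 1.38 CPM (exact two-sided permutation p = 0.543; log2 fold change 0.09 ± 0.17). The sign of Arntl turned without BHLKO replicate 5 and that of Hif1a without Alb-Cre replicate 5. Counts over whole genes need not fall when floxed exons are removed, and the driver is not directed at lung, so these levels do not check the genotype labels. Of the Y-linked genes, Ddx3y (1.98 ± 0.715 and 2.44 ± 0.635 CPM), Kdm5d (8.73 ± 1.52 and 11.6 ± 2.23), Eif2s3y (10.4 ± 2.75 and 12.7 ± 2.92) and Uty (2.61 ± 1 and 1.53 ± 0.394) were read in all 8 libraries and none passed the test, also when adjusted over the list alone.

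Lungs of BHLKO mice differed from controls in 306 of 13517 tested genes (2.26%): 140 rose and 166 fell. The largest rise was in Serpina3h, a serine protease inhibitor of the alpha-1-antichymotrypsin family, from 1.22 ± 0.614 to 32.1 ± 5.32 CPM, a 24.8-fold difference. Trim12a, of the tripartite motif family, had 31.9 ± 2.6 CPM in Alb-Cre and 0 counts in every BHLKO library. Sox11, a developmental transcription factor, fell 7.62-fold, and Rec8, the meiotic cohesin subunit, fell 14.5-fold. Of the calls, 109 were at least 2-fold and 297 had group values that did not overlap. Among all tested genes 9.4% had such values, where 2.9% would by chance. The count of calls ranged from 131 without Alb-Cre replicate 1 to 520 without Alb-Cre replicate 5. In every one of those fits the 306 genes kept their direction, and 105 stayed called in all 8. Where group values do not overlap, leaving out a library cannot turn the direction, so kept direction is no separate support for those 297 calls.

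Among the 10 largest rises, Serpina3h (chromosome 12, 104247905 to 104253669) rose by log2 4.63 ± 0.26 (edgeR adjusted p = 3.91e-08). Rtkn2, a marker of alveolar type 1 cells, rose 6.15-fold from 3.64 ± 1.39 to 22.1 ± 5.51 CPM. Steap3, an endosomal ferrireductase, rose 3.29-fold from 20.3 ± 2.91 to 66.7 ± 15.3 CPM, and Tor3a, a torsin family ATPase, 3.07-fold from 17.9 ± 2.19 to 55.1 ± 8.44 CPM. Tc2n and the interferon-induced antiviral gene Rsad2 each rose 3.23-fold, to 12.7 ± 1.57 and 12.8 ± 3.12 CPM. Myl1, a skeletal muscle myosin light chain, rose 5.24-fold from 11.6 ± 2.41 to 61.6 ± 27.7 CPM. The remaining rises, at low levels, were in Greb1 (5.95-fold, to 2.27 ± 0.682 CPM), Ctse (4.73-fold, to 3.79 ± 1.36 CPM) and the receptor kinase antagonist Spry2 (3.18-fold, to 6.63 ± 2.28 CPM). The calls of Greb1, Myl1, Ctse and Spry2 were each lost on leaving out at least 1 library, Alb-Cre replicate 4 in every case, while the other 6 were kept in all 8 such fits.

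The 3 largest falls were neighbours. Trim34a (chromosome 7, 104244457 to 104262234), Trim5 (104263386 to 104288094) and Trim12a (104299894 to 104315466) lie side by side. Trim12a was at least 483-fold lower in BHLKO against a floor of 3 counts over the group (edgeR adjusted p = 3.29e-09). Trim34a had 249 counts over the Alb-Cre libraries and 2 over the BHLKO libraries, a ratio of 120 with a 95% exact counting interval of 32.8 to 995; both BHLKO counts lie in replicate 2, and the other 3 libraries have 0. Trim5 had 199 and 4 counts, a ratio of 47.9 (18.4 to 177). These genes have close paralogs next to them, and reads that match several copies could have been assigned to another copy or dropped. The same tools are listed for all libraries. Such handling could therefore add to the difference only where gene sequences, copies or paralog levels differ between the groups. All 3 genes lie within 20 Mb of Arntl, and linked alleles there were not told apart from an effect of liver genotype. Their neighbours Trim12c and Trim30a, singled out after their values were seen, differed in opposite directions and did not pass. Trim12c was at 4.02 CPM in Alb-Cre and 6.21 CPM in BHLKO (edgeR adjusted p = 0.245). Trim30a was at 4.51 and 2.68 CPM (edgeR adjusted p = 0.476).

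Sox11 (chromosome 12, 27334264 to 27342574) fell from 33.7 ± 6.56 to 4.38 ± 0.769 CPM (edgeR adjusted p = 1.31e-07). Rec8 fell from 8.35 ± 1.57 to 0.553 ± 0.588 CPM (log2 −3.85, and −4.78 without BHLKO replicate 3), the adhesion molecule Cdh26 8.33-fold from 5.36 ± 3.83 to 0.628 ± 0.348 CPM (log2 −3.06, and −2.42 without Alb-Cre replicate 4), and the monocyte-attracting chemokine Ccl12 6.3-fold from 5.38 ± 1.66 to 0.839 ± 0.261 CPM. Pacsin1 (7.48-fold), the lectin-like receptor Clec2i (5.59-fold) and the class II histocompatibility gene H2-Eb2 (5.39-fold) fell to under 1 CPM. Their calls were lost in at least 5 of the 8 fits that left out a library, Alb-Cre replicates 1 and 4 and BHLKO replicates 2, 4 and 5 among them. Serpina3h, Clec2i, H2-Eb2 and Ccl12 belong to families of similar genes. Counting of shared reads could add to their difference only where gene sequences, copies or levels of similar genes differ between the groups.

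**Figure D1:**
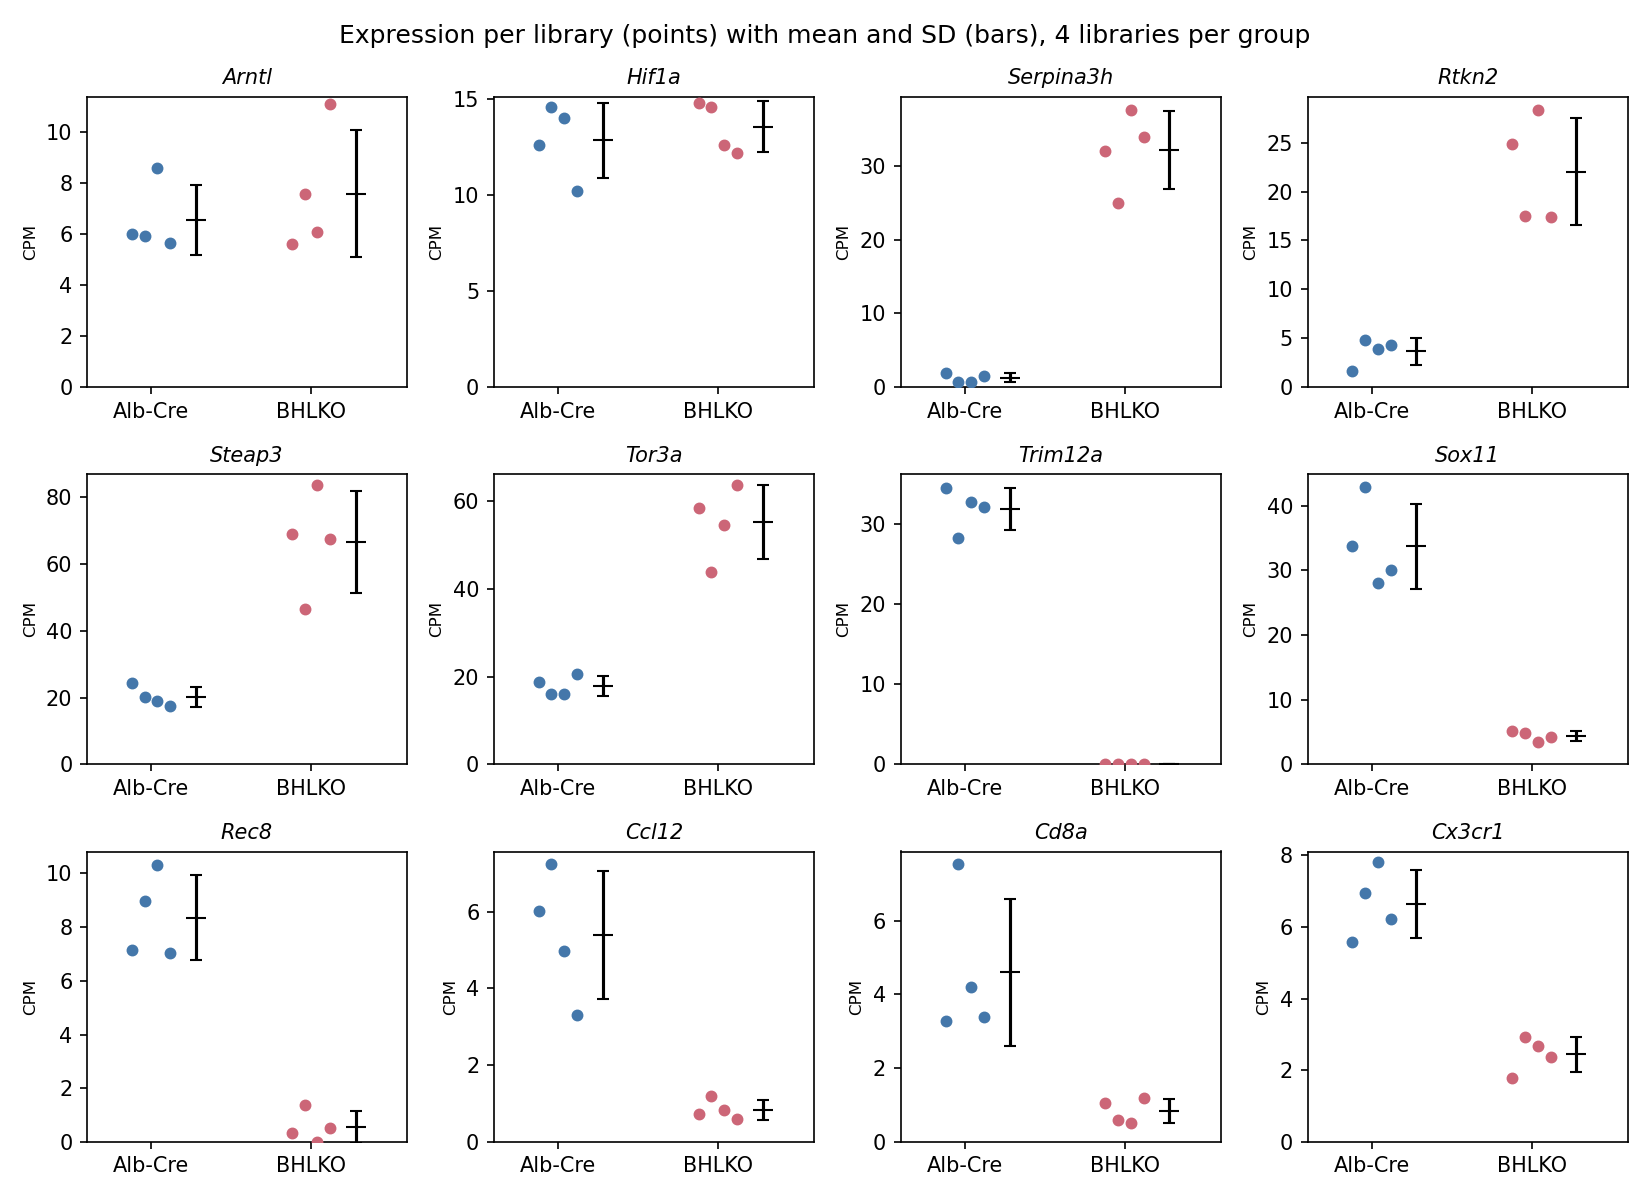
CPM (vertical axes, from 0) of Arntl, Hif1a and 10 called genes in each of the 4 Alb-Cre and 4 BHLKO libraries; points are libraries, horizontal marks and bars the mean and SD. Arntl and Hif1a overlap between the genotypes, while Trim12a has 31.9 CPM on average in Alb-Cre and 0 in BHLKO.

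Called genes were unevenly placed on the chromosomes. Chromosome 12, which carries Hif1a, had the highest share, with 29 of 459 tested genes called (6.32%, against 2.12% elsewhere; Fisher's exact test, adjusted p = 1.21e-05 over the chromosomes). Chromosome 1 had 30 of 763 (3.93%, adjusted p = 0.0235) and chromosome 6 25 of 670 (3.73%, adjusted p = 0.0768), whereas chromosome 5 had 5 of 857 (0.583%, adjusted p = 0.00121). Chromosome 7, which carries Arntl, had 24 of 1050 (2.29%, adjusted p = 1). Within 20 Mb of Arntl or Hif1a, 21 of 517 tested genes were called (4.06%), against 2.19% elsewhere (Fisher's exact test, p = 0.00946). Trim12a, Trim34a, Trim5, Akap5, Bag3 and Lyve1 are among them, as are Coro1a, Il21r, Itgal and Prkcb, leukocyte genes that fell. Taken alone at that distance, Arntl had 13 of 321 (Fisher's exact p = 0.0364) and Hif1a 8 of 196 (p = 0.0887). Within 5 Mb the counts were 1 of 52 for Arntl (p = 1) and 5 of 68 for Hif1a (p = 0.0188), within 10 Mb 6 of 118 (p = 0.0517) and 6 of 110 (p = 0.0389), with 12 of 228 for both together (p = 0.00584), and within 40 Mb 15 of 524 (p = 0.366) and 21 of 351 (p = 5.07e-05), all by Fisher's exact test. Of 142 bins of 20 Mb, drawn like the other distances after the data were seen, 4 had more called genes than chance gives at an adjusted hypergeometric p under 0.05, and none of the 4 holds Arntl or Hif1a: chromosome 1 from 120 Mb (11 of 103, with Steap3 and Ctse), chromosome 6 from 120 Mb (12 of 134, with Clec2i), and chromosome 12 from 20 Mb (7 of 58, with Sox11 and Rsad2) and from 100 Mb (10 of 129, with Serpina3h and Tc2n). The bin with Hif1a had 5 of 83 (adjusted p = 0.947). With the genes of chromosomes 1, 6, 7 and 12 left out, an alternative chosen after seeing the data, 172 genes were called. Of the 20 largest changes named by the rule, 13 lay on these chromosomes, which hold 22.1% of tested genes. For these genes, linked strain alleles and an effect of liver genotype were not told apart.

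**Figure D2:**
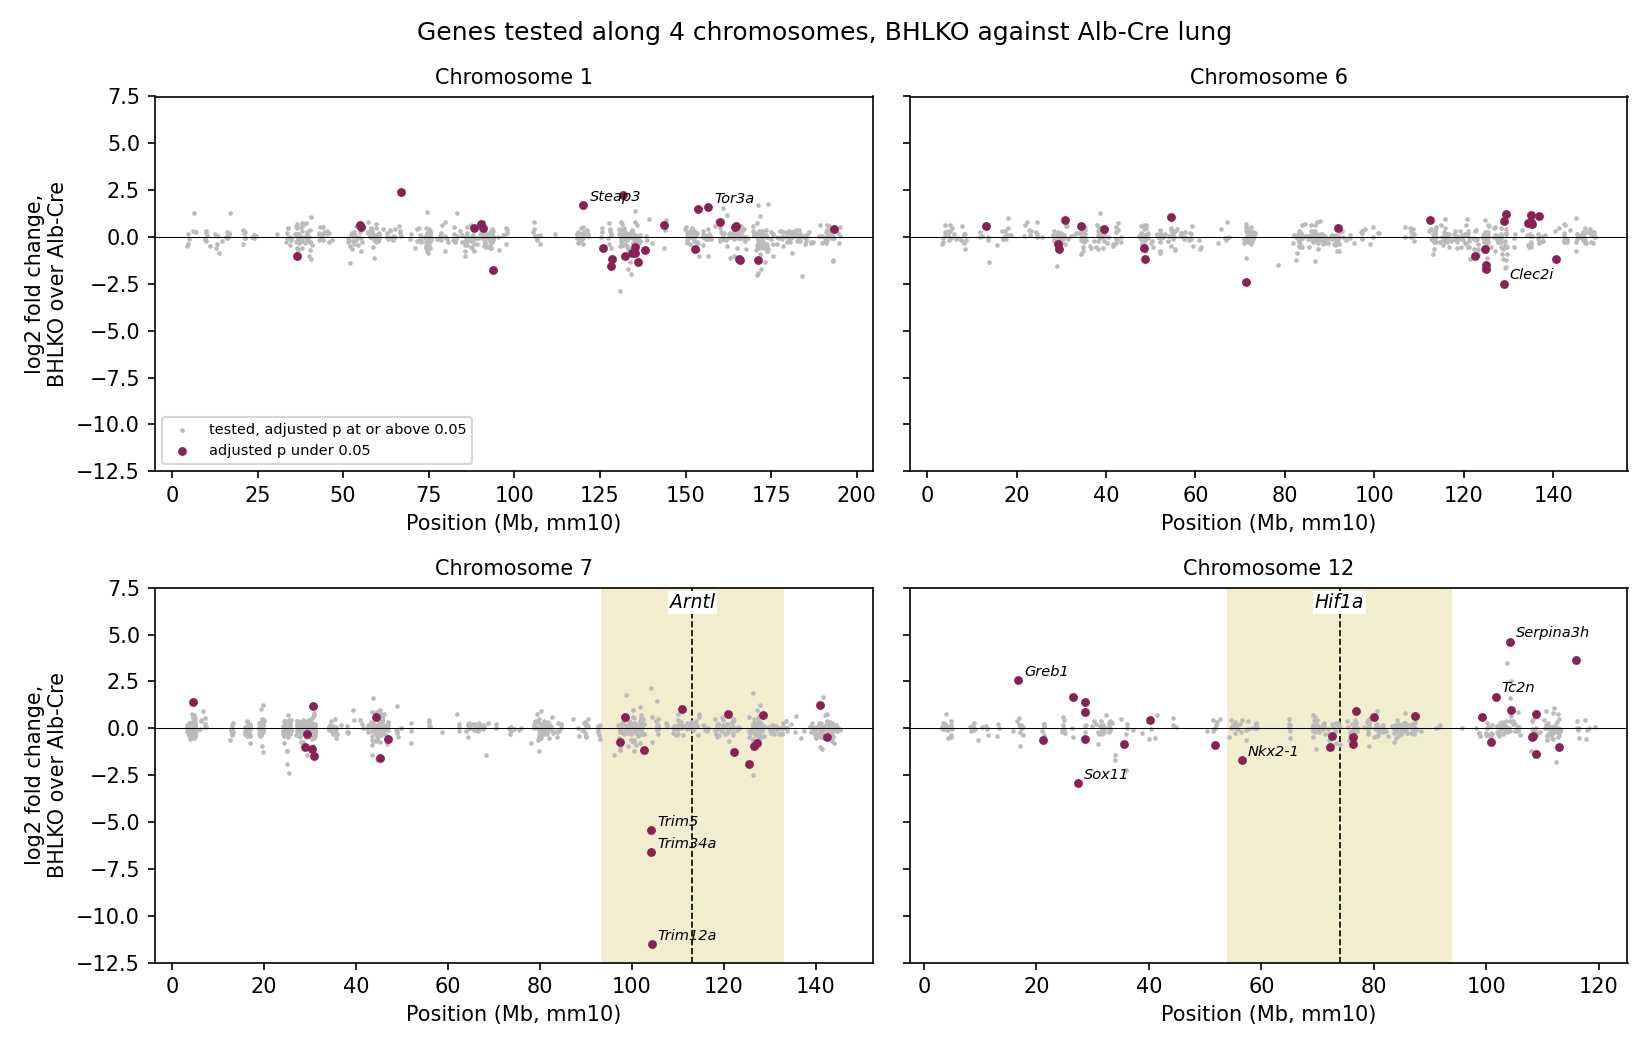
Log2 fold change (vertical axis, BHLKO over Alb-Cre) of each tested gene by its start position in Mb (horizontal axis, mm10) on chromosomes 1, 6, 7 and 12; dark points have an adjusted p under 0.05, dashed lines mark Arntl and Hif1a and shaded bands 20 Mb to either side. Trim12a is drawn at its fitted −11.53, which is no bound since its BHLKO counts are 0; called genes of both directions lie in the bands and outside them.

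Several lymphocyte genes fell in BHLKO lung. Of 13 tested T cell and NK cell genes, 4 fell, 0 rose and 9 did not pass, and 10 fell when adjusted over the list alone (median log2 fold change −1.15; all 13 below 0). The co-receptor genes Cd8a and Cd4 fell 5.26-fold (4.59 ± 1.99 to 0.842 ± 0.334 CPM) and 2.83-fold (13.8 ± 4.92 to 4.87 ± 1.62 CPM), the T cell receptor subunit Cd3d 2.35-fold and Cd6 3.17-fold. Of 9 B cell and plasma cell genes, Cd22, an inhibitory B cell receptor, fell 2.82-fold (21.1 ± 7.5 to 7.49 ± 2.83 CPM), 8 did not pass, and 7 fell when adjusted over the list alone (median −1.92). Fcmr was at 42.2 ± 25.8 and 5.66 ± 1.49 CPM (adjusted p = 0.0657) and Cd79a at 3.91 ± 2.28 and 1.02 ± 0.49 CPM (adjusted p = 0.0686). Camera gave adjusted p = 7.05e-12 for the T cell and NK cell list and 5.39e-10 for the B cell list, and each had adjusted p = 0.248 with an estimated correlation. Alb-Cre replicate 5 scored −0.01 for T cell and −0.29 for B cell genes, against 0.66 to 0.95 and 0.59 to 1.8 in the other Alb-Cre libraries. Adipocyte genes, a check for attached tissue, scored 1.84 and 1.41 in Alb-Cre replicates 1 and 4, where the B cell score was also highest (1.48 and 1.8). They scored −1.42 and −1.1 in Alb-Cre replicates 2 and 5. T cell scores were 0.66, 0.87, 0.95 and −0.01 in the same order. In BHLKO replicates 2, 3, 4 and 5 adipocyte genes scored 0.14, −0.93, −0.62 and 0.69. The B cell scores there ran in the reverse order (−1.18, −0.08, −0.94 and −1.39). The calls of Cd4 and Cd3d were lost without Alb-Cre replicate 1 or 4 or BHLKO replicate 4, those of Cd6 and Cd22 on leaving out any of at least 5 libraries, and that of Cd8a in none.

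Among 13 genes of interstitial macrophages and monocytes, the fractalkine receptor Cx3cr1 fell 2.71-fold (6.64 ± 0.959 to 2.44 ± 0.488 CPM) and 12 did not pass; adjusted over the list alone, 1 fell. Treml4 (log2 −1.17 ± 0.41), Folr2 (−0.8 ± 0.38) and Ly6c2 (−0.96 ± 0.44) had adjusted p of 0.161, 0.342 and 0.352. The list median was −0.22 (camera adjusted p = 0.0049; adjusted p = 0.248 with an estimated correlation). The list of thymus, thyroid and esophagus tissue, a check for neighbouring organs, had a median of −1.11 over 6 genes of which 0 passed and 1, Cd8b1, fell when adjusted over the list alone (camera adjusted p = 0.0349; adjusted p = 0.248 with an estimated correlation). Cd8b1, which mature T cells also express, was at 7.19 ± 2.25 and 3.26 ± 0.962 CPM, Dntt at 2.34 ± 2.53 and 0.621 ± 0.307 CPM, Krt13 at 14.6 ± 10.2 and 6.79 ± 5.42 CPM and Krt5 at 6.07 ± 9.4 and 1.45 ± 1.27 CPM; Krt5 changed sign without Alb-Cre replicate 4, Krt13 went from log2 −1.1 to −0.5 without it, and Dntt from −1.8 to −0.86 without Alb-Cre replicate 2.

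The heat shock and cold-inducible list held 3 calls. Of its 13 genes, 2 rose, 1 fell and 10 did not pass, and adjusted over the list alone 10 rose and 2 fell (median 0.69). The mitochondrial chaperonin Hspd1 rose 1.47-fold (57.6 ± 7.69 to 85 ± 11.9 CPM) and the co-chaperone Bag3 1.61-fold (75.5 ± 13.7 to 122 ± 23.4 CPM), while Cirbp, a cold-inducible RNA-binding protein, fell 1.77-fold (77.1 ± 17.2 to 43.6 ± 8.36 CPM). Hspe1, the partner of Hspd1, was at 145 ± 30 and 221 ± 31.6 CPM (adjusted p = 0.0508). Camera gave adjusted p = 1.04e-07 for the list (adjusted p = 0.248 with an estimated correlation). Each of the 3 calls was lost in at least 4 of the 8 fits that left out a library, Alb-Cre replicates 1, 2 and 4 in each case.

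The immediate-early list had 0 of 16 genes past the test, and 0 when adjusted over the list alone (median 0.57; camera adjusted p = 0.000111; adjusted p = 0.52 with an estimated correlation). Jun was at 294 ± 48.7 and 390 ± 43.6 CPM (adjusted p = 0.0931), and Nr4a2, Ier2 and Egr2 had log2 fold changes of 0.76 ± 0.32, 0.42 ± 0.18 and 0.71 ± 0.33. Of 14 glucocorticoid-responsive genes, the kinase gene Sgk1 rose 1.36-fold (114 ± 17.1 to 155 ± 6.36 CPM) and 13 did not pass; adjusted over the list alone 1 rose (median 0.31; camera adjusted p = 0.000923; adjusted p = 0.457 with an estimated correlation). Sult1a1, Mt2 and Cebpd had log2 fold changes of 0.31 ± 0.11, 0.41 ± 0.15 and 0.63 ± 0.25. Alb-Cre replicate 5 scored 0.13, 0.41 and 0.37 for the heat shock, immediate-early and glucocorticoid lists, the last 2 within or above the BHLKO ranges of 0.01 to 0.56 and 0.13 to 0.29. Of 15 genes of the unfolded protein and integrated stress response, 0 passed and 3 rose when adjusted over the list alone (median 0.25; camera adjusted p = 0.0121; adjusted p = 0.435 with an estimated correlation). The chaperone Hspa5 was at 156 ± 27.5 and 230 ± 47.8 CPM, Atf4 at 149 ± 7.3 and 185 ± 14.2 CPM, Manf at 159 ± 22 and 205 ± 17.1 CPM and Creld2 at 47 ± 4.62 and 57.9 ± 6.48 CPM. Among 12 targets of the xenobiotic receptor AHR and of NRF2, the monooxygenase gene Cyp1a1 rose 1.83-fold (17.3 ± 1.57 to 31.7 ± 9.41 CPM), 11 did not pass, and 4 rose when adjusted over the list alone (median 0.14; camera adjusted p = 0.0349; adjusted p = 0.248 with an estimated correlation). Nqo1 (log2 1.09 ± 0.3), Gclc (0.34 ± 0.11) and Gclm (0.28 ± 0.09) had adjusted p of 0.07, 0.118 and 0.143. The calls of Sgk1 and Cyp1a1 were each lost in 6 of the 8 fits that left out a library.

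Of 9 platelet and megakaryocyte genes, Treml1, a receptor stored in platelet granules, rose 2.12-fold (9.01 ± 0.457 to 19.1 ± 4.69 CPM), 8 did not pass, and 6 rose when adjusted over the list alone (median 0.84; camera adjusted p = 1.01e-06; adjusted p = 0.248 with an estimated correlation). Pf4 was at 136 ± 14.3 and 242 ± 85.6 CPM, Gp1bb at 28.3 ± 5.62 and 47.5 ± 15.1 CPM and Itga2b at 47.9 ± 5.17 and 67.7 ± 18.3 CPM. Of 4 tested red blood cell genes, too few for camera, the heme synthesis enzyme Alas2, named after its values were seen, rose 1.81-fold from 421 to 764 CPM, and 3 rose when adjusted over the list alone (median 0.96). In the fibroblast and extracellular matrix list the metalloproteinase inhibitor Timp1 rose 1.68-fold (11.5 ± 1.3 to 19.5 ± 2.21 CPM) and the collagen cross-linking enzyme Lox 1.8-fold (19.1 ± 4.83 to 34.7 ± 7.41 CPM), 13 of 15 did not pass, and 4 rose when adjusted over the list alone (median 0.26; camera adjusted p = 0.000614; adjusted p = 0.248 with an estimated correlation). Fn1 was at 278 ± 45.8 and 374 ± 26.8 CPM (adjusted p = 0.0562) and Col13a1 at 27.4 ± 4.04 and 36.7 ± 5.48 CPM. All 14 cardiac muscle genes, which lung expresses in pulmonary vein walls, lay above 0 with a median of 0.92, 0 passed, and 0 passed when adjusted over the list alone (camera adjusted p = 1.92e-06; adjusted p = 0.457 with an estimated correlation). Actc1 was at 470 ± 160 and 1200 ± 610 CPM, Ttn at 19.7 ± 5.64 and 43.4 ± 19.9 CPM, Tnnc1 at 37.1 ± 6.67 and 63.1 ± 20.3 CPM and Ryr2 at 9.13 ± 1.82 and 18.5 ± 8.81 CPM. The cardiac score was −0.44 in BHLKO replicate 3, within the Alb-Cre range of −0.95 to 0.15, and 1.15 in BHLKO replicate 5; these libraries were also lowest and highest for the skeletal muscle list (−1.18 and 1.86; median log2 fold change 0.87). Among BHLKO libraries Myl1 was likewise lowest in replicate 3 (28 CPM) and highest in replicate 5 (85.1 CPM). Its lowest BHLKO value still lay above the Alb-Cre range of 8.24 to 13.4 CPM. How far muscle content of the samples accounts for its rise was not tested. Leaving out any of at least 5 libraries ended the calls of Timp1 and Lox.

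Endothelial signalling genes gave single calls. Of 16 genes of BMP9 and ALK1 signalling, the inhibitory SMAD gene Smad6 rose 1.74-fold (311 ± 68.3 to 540 ± 81.5 CPM), 15 did not pass, and 4 rose when adjusted over the list alone (median 0.14; camera adjusted p = 0.0471; adjusted p = 0.56 with an estimated correlation). Its co-receptor Eng was at 802 ± 116 and 1160 ± 254 CPM, Id1 at 515 ± 97.1 and 749 ± 153 CPM and Tmem100 at 603 ± 112 and 766 ± 35.8 CPM. The call of Smad6 was lost without Alb-Cre replicate 1, BHLKO replicate 2 or BHLKO replicate 5. In 4 vascular lists that camera did not call, single members rose and are named after their values were seen. The capillary diaphragm gene Plvap rose 1.6-fold to 1410 CPM (1 of 11 general capillary genes; camera adjusted p = 0.0596), and the lymphangiogenic factor Vegfd 1.39-fold to 283 CPM (1 of 21 angiogenesis genes; camera adjusted p = 0.161). Prostacyclin synthase, Ptgis, rose 1.38-fold to 314 CPM (1 of 22 vasoactive genes; camera adjusted p = 0.167), and Lyve1 2.02-fold to 475 CPM (1 of 12 arterial, venous and lymphatic genes; camera adjusted p = 0.902). Adjusted over the list alone, 2, 1, 1 and 2 genes rose in these lists, and 1 fell in the last. Leaving out a library never ended the call of Plvap, while those of Vegfd, Ptgis and Lyve1 were lost in at least 5 of 8 fits. In aerocytes 0 of 10 and in pericytes 0 of 11 genes passed; adjusted over the list alone, 0 passed and 1 fell.

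Camera did not call the lists tied to the deleted factors and to blood flow. Of 24 HIF targets, the collagen prolyl hydroxylase P4ha1, the single call, rose 2.44-fold (14.2 to 34.8 CPM, lost without Alb-Cre replicate 2), 23 did not pass, and adjusted over the list alone 2 rose and 1 fell (median 0.01; camera adjusted p = 0.709). The clock list had 0 of 18 genes past the test, and 0 when adjusted over the list alone (median 0.2; camera adjusted p = 0.161). The clock score was −0.12 to 0 in Alb-Cre and 0.02 to 0.14 in BHLKO (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.112 over the lists). Of 16 nitric oxide and cyclic GMP genes 0 passed, and adjusted over the list alone 1 rose and 2 fell (median 0.02; camera adjusted p = 0.973). Fry without regard to direction gave adjusted p = 0.00337 for HIF targets, 0.00094 for nitric oxide genes and 0.0629 for clock genes. That test gave similar or lower values for other lists that camera did not call. Among them were interferon-stimulated genes (fry adjusted p = 1.41e-06), alveolar type 2 genes (0.00337) and pericytes (0.00897). The values therefore do not set HIF targets or nitric oxide genes apart. Each of the 39 lists that camera tested had an adjusted p above 0.05 with an estimated correlation, while fry, directional, called 3 (T cells and NK cells, interstitial macrophages and monocytes, and xenobiotic targets, each with adjusted p = 0.041). Camera called 13 lists, 9 higher and 4 lower, and other groupings of the same 8 libraries gave up to 15.

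**Figure D3:**
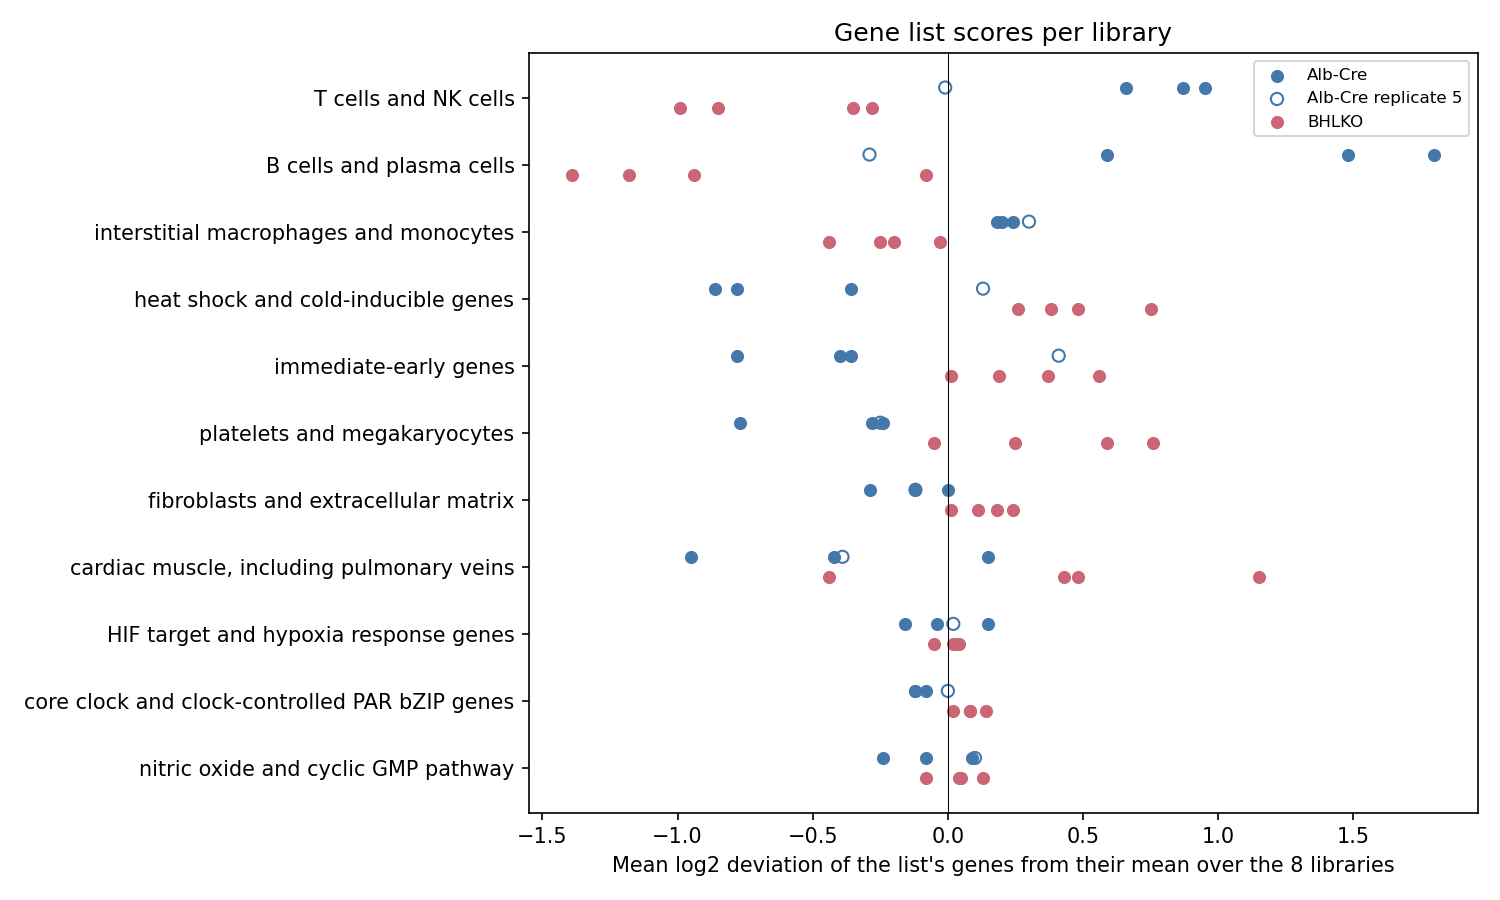
Score of 11 gene lists in each library: the mean log2 deviation of the list's genes from their mean over the 8 libraries (horizontal axis), with blue points for Alb-Cre, an open circle for Alb-Cre replicate 5 and red points for BHLKO. T cell and NK cell scores are −0.99 to −0.28 in BHLKO and −0.01 to 0.95 in Alb-Cre, and HIF target scores overlap.

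Of the lung's own cell types, alveolar type 1 genes moved in both directions. Of 11 genes Rtkn2 and Pdpn (1.39-fold, 33.2 ± 2.87 to 46.3 ± 3.14 CPM) rose, Akap5 fell 1.4-fold (131 ± 19 to 93.6 ± 11.8 CPM), 8 did not pass, and adjusted over the list alone 3 rose and 2 fell (median 0; camera adjusted p = 0.161). Aqp5 was at 414 ± 62.1 and 319 ± 30.2 CPM (adjusted p = 0.0878). Of 12 alveolar type 2 and surfactant genes, Sftpd rose 1.34-fold to 1920 CPM (lost without Alb-Cre replicate 4 or BHLKO replicate 2) and 11 did not pass; 1 rose when adjusted over the list alone (median 0.09; camera adjusted p = 0.202). In smooth muscle Tpm2 (1.66-fold, to 47.4 ± 7.12 CPM) and Hhip (1.38-fold, to 67.3 ± 4.38 CPM) rose and 13 of 15 did not pass; adjusted over the list alone 3 rose and 2 fell (median 0.2; camera adjusted p = 0.115). Des was at 451 ± 74.8 and 576 ± 82.6 CPM and Mustn1 at 134 ± 10.2 and 112 ± 10.2 CPM. The calls of Pdpn, Akap5, Tpm2 and Hhip were each lost in at least 5 of the 8 fits that left out a library.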

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

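The tests of neighbouring calls, lymphoid stroma, alveolar dilution, handling, and the groupings of the libraries for rises, falls and lists were chosen only after the results were seen; those of all changed genes over groupings, of the 20 Mb windows and of the Y-linked genes were chosen before the data were examined.

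The 8 libraries can be split into 4 and 4 in 35 ways. Only the real split called as many as 306 genes, against at most 11 in the others (1 of 35 splits). For the 140 rises and 166 falls, no other split called more than 10 in 1 direction (1 of 35 splits each). These counts argue against chance but cannot exclude it, since 1 of 35 is the smallest share that 35 splits can give. Every other split also mixes the genotypes, so the splits do not tell genotype from other differences between the groups. Chance stays open for the 13 lists called by camera, since 6 of 35 splits called as many and the highest other called 15. Most of these splits exchange Alb-Cre replicate 5 for a BHLKO library.

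The first pattern is the placing of called genes. Within 20 Mb of Arntl or Hif1a the share of called genes was 1.85 times that elsewhere (Fisher's exact p = 0.00946), as linked alleles carried along with the floxed loci would give, but it holds 21 of 301 called genes with a position, and within 5 Mb the share was 0.849 times that elsewhere near Arntl (Fisher's exact p = 1) and 3.28 times near Hif1a (p = 0.0188), and within 10 Mb 2.27 times (p = 0.0517) and 2.44 times (p = 0.0389). The calls within 20 Mb include the fallen leukocyte genes Coro1a, Il21r, Itgal and Prkcb, so this share and the second pattern below are not independent. A scatter that ignores position is argued against: 142 called genes had another within 1 Mb, against a median of 115 in 10000 shuffles (permutation p = 0.0055). Co-regulation of neighbours stays open: 61.8% of 89 neighbouring pairs moved the same way (95% exact interval 50.9 to 71.9), but shuffles gave a median of 67 pairs, and 62.7% would result if all further pairs moved together. Strain differences away from the floxed loci, as in the 4 bins on chromosomes 1, 6 and 12, and an effect of liver genotype on lung may both contribute and were untested.

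The second pattern is the fall of lymphocyte genes, 4 of 13 in the T cell and NK cell list. Dilution of lung RNA by other tissue is argued against, since the alveolar type 1 and type 2 genes had a median log2 fold change of 0.05. Its 95% bootstrap interval of −0.03 to 0.25 resamples the 23 genes and not the libraries. Scores per library differed by 0.24 for type 1 and −0.07 for type 2 genes (BHLKO minus Alb-Cre, pooled SD 0.09 and 0.15). Less lymph node or follicle tissue in the BHLKO samples stays open: Chst4, Ccl19 and Cxcl13, the 3 tested of 8 stroma genes listed after some of their values were seen, had a median of −1.63, but their score gave an exact permutation p of 0.0571 and 3 genes are too few to decide. A lower number of lymphocytes in BHLKO lung may account for the pattern equally and was untested, as was attached tissue with adipocytes. The adipocyte score was highest in the Alb-Cre libraries with the highest B cell scores, replicates 1 and 4. In BHLKO the order was the reverse, with the highest adipocyte score (0.69) and the lowest B cell score (−1.39) both in replicate 5.

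The third pattern is that camera called the heat shock and immediate-early lists higher, with 2 of 13 and 0 of 16 genes rising and adjusted p of 0.248 and 0.52 with an estimated correlation. A difference in handling before freezing may raise both. The heat shock score separated the genotypes (exact permutation p = 0.0286, the smallest possible, which 10 of 39 lists reach; adjusted p = 0.112) and the immediate-early score did not reach the threshold (exact permutation p = 0.114), with Alb-Cre replicate 5 among the BHLKO libraries. The order and duration of dissection are not in the labels, so handling and genotype cannot be told apart.

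The bound set beforehand for a difference in sex between the groups asked for every Y-linked gene above 1 CPM in every library. It was missed, since Uty was at 0.946 CPM in BHLKO replicate 3. Summed over Ddx3y, Kdm5d, Eif2s3y and Uty the libraries held 22.3 to 33.8 CPM. Kdm5d was at least at 6.79 CPM in Alb-Cre and 9.55 CPM in BHLKO, and Eif2s3y at least at 8.32 and 10 CPM. Y-linked expression in every library of both groups argues against a difference in sex between them.

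A library stood apart from the other 3 of its group in 14 of 250 groups of 4 values examined (5.6%), close to the 1 in 20 that chance gives. In Alb-Cre replicate 4 these were Arntl (8.58 CPM, others 5.63 to 6.02), Cdh26 (11.1 CPM), Krt5 (20.2 CPM, others 0.967 to 1.85) and Gclm (94.6 CPM), and the scores of aerocyte (−0.09) and skeletal muscle genes (0.25). In BHLKO replicate 2 they were Spry2 (10 CPM), Trim34a (0.163 CPM, others 0) and Nqo1 (10.3 CPM). BHLKO replicate 5 stood apart in Cd6 (0.681 CPM) and Des (700 CPM), BHLKO replicate 3 in Lox (23.7 CPM, others 37.5 to 39.9) and BHLKO replicate 4 in the interferon score (0.08). The platelet score of Alb-Cre replicate 1 was −0.77, against −0.28 to −0.24 in the other 3.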

How the results depend on the processing

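The alternatives that leave out genes by position and the permutation test of list scores were chosen after seeing the data. All 306 called genes that were tested kept their direction under every scaling, filter, test, block and left-out library. This is no separate support, since they were called on the same libraries and 297 of them have group values that do not overlap. Counts under the other scalings, filters, limma-voom, the fit without robust estimation and 1 surrogate variable stayed between 279 and 314. DESeq2 called 681 genes (318 higher, 363 lower), all 306 among them. It made more false calls on the data simulated with edgeR dispersions, which does not show how many of its further calls here are false. An adjusted p under 0.1 gave 579 genes (266 and 313), and a 1.5-fold minimum left 217, 90 of them higher. Without chromosomes 1, 6, 7 and 12, which leaves fewer genes to test, 172 were called (74 and 98). Leaving out 1 library gave 131 to 520 genes, 53 to 267 higher and 78 to 253 lower. Removing any library except BHLKO replicate 3 moved the count by more than 1.5 times, lowest without Alb-Cre replicate 1; the count rose only without Alb-Cre replicate 5 and, to 319, without BHLKO replicate 3. The cause was not tested.

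Samples of the same number showed little shared deviation, with correlations from −0.006 to 0.066 by title and −0.006 to 0.038 by description. So few pairs cannot decide whether the numbers pair the samples. A replicate block by the numbers of the titles called 396 genes and by those of the descriptions 160 (81 higher, 79 lower).

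Of the lists, camera called 11 to 18 under the other settings, 0 with an estimated correlation, fry 3 and the exact permutation test of list scores 0, whose smallest adjusted p was 0.112. Leaving out 1 library gave 12 to 15. The difference in Arntl between the group means ran from −0.115 CPM (without BHLKO replicate 5) to 1.74 CPM, and in Hif1a from −0.163 CPM (without Alb-Cre replicate 5) to 1.29 CPM; on the log2 scale Arntl ran from −0.03 to 0.38 and Hif1a from −0.01 to 0.15. Krt5 ran from −2.59 to 0.05, which is its value without Alb-Cre replicate 4, and Ddx3y turned to 0 with the block by descriptions. Among named genes and lists, leaving out a library ended a call 124 times and added 21, and the other settings ended 65 and added 38. With 4 simulated libraries a group, 26.9% of 1.5-fold changes were found.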

Other observations

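Outside the genes chosen by rule, several calls at higher levels were singled out after their values were seen. Nkx2-1, a transcription factor that drives surfactant genes in lung epithelium, fell 3.27-fold, from 198 ± 10.4 to 60.6 CPM (edgeR adjusted p = 3.91e-08), with no overlap between the groups. Its known target Sftpc was at 33300 and 34300 CPM (adjusted p = 0.847) and Sftpd rose. Nkx2-1 lies on chromosome 12 (56531958 to 56536908), within 20 Mb of Hif1a. Mgp, an inhibitor of calcification and of BMP signalling, rose 2.15-fold from 4150 to 8920 CPM (adjusted p = 2.84e-06). It lies on chromosome 6 (136872435 to 136875823), and Cxcr4 on chromosome 1 (128588199 to 128592293), each in a 20 Mb bin with more called genes than chance gives. The chemokine receptors Cxcr4 (82.5 to 37.1 CPM) and Ccr7 (29.5 to 10.5 CPM) fell 2.22-fold and 2.81-fold. All 4 calls were kept in each of the 8 fits that left out a library.

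In lists that camera did not call, single members changed. The mast cell chymase Cma1 fell from 6.92 to 1.29 CPM (1 of 6 genes; camera adjusted p = 0.284) and the cholesterol synthesis enzyme Hmgcs1 from 157 to 73.2 CPM (1 of 14; camera adjusted p = 0.543). Plet1 rose from 22.1 to 35.1 CPM (1 of 12 alveolar macrophage genes; camera adjusted p = 0.128), and Rsad2 was the single called gene among 17 interferon-stimulated genes (camera adjusted p = 0.992). Of the 8 fits that left out a library, the call of Plet1 was kept in 1 (without Alb-Cre replicate 5) and that of Hmgcs1 in 2 (without Alb-Cre replicate 1 or 5), while Cma1 and Rsad2 were kept in all 8; of 8 other settings Plet1 was kept in 4. Adjusted over the list alone these 4 lists had 1 fall, 1 fall, 1 rise, and 3 rises with 4 falls. None of the tested genes passed in the lists of hepatocytes (8 genes; camera adjusted p = 0.161), skeletal muscle (8; 0.161), adipocytes (12; 0.41), mesothelium (8; 0.543), ciliated cells (13; 0.579), club and secretory cells (10; 0.902) or neutrophils (12; 0.965). The same holds for cell cycle (11; 0.314), inflammatory cytokine (14; 0.39), fatty acid oxidation (15; 0.0803) and cartilage genes (2, too few for camera). Adjusted over the list alone, 1 fatty acid oxidation gene rose and 0 genes passed in the others. The hepatocyte score was 3.24 in BHLKO replicate 5 and 1.39 in Alb-Cre replicate 5, with Serpina1b at 2.3 and 29.1 CPM in the genotypes (adjusted p = 0.142).

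The series title concerns a time-dependent response, and these lungs come from circadian time 16 alone, so a phase difference cannot be seen here. If liver genotype acts on lung through the blood, the changes of Plvap and Smad6 should return in floxed littermates compared with and without the driver, whereas alleles linked to the floxed loci should return in floxed mice lacking the driver. Flow cytometry of perfused lung would tell whether the lower Cd8a and Cd4 reflect fewer cells, and lungs frozen in alternating genotype order would test handling for Hspd1, Bag3 and Jun.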
